A study of Homo sapiens with 6 samples.

How the data were processed

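The data are 3 TRIM24 peak lists, from LNCaP cells under vehicle, LNCaP cells under 10 nM DHT for 4 h and LNCaP-abl cells under vehicle, with 1 ChIP library for each condition. The series also names 3 input libraries, which were not analysed here. Per the submitters' processing notes, the tools were FastQC 0.10.0, Bowtie 0.12.7 and MACS2 2.0 and the genome build was hg19. Each list carries the name of a single library, and peaks appear to have been called per library. Whether the inputs served as control, how reads were filtered and which cutoff was used are not given in the sources used here. The lists have 5 columns without a header: chromosome, start, end, peak name and score. The deposited score is −log10 of a p-value or q-value, as MACS2 writes it in the authors' lists, and the lists do not say which of them it is. It starts just above 2 in every list, where a cutoff of 0.01 would lie. The score is the authors' own and was used to rank, describe and filter peaks; it grows with depth, which the lists do not give. Starts were converted from counting from 0 to counting from 1 for printing.

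Groups were taken from the labels. Peaks were compared by overlap of at least 1 bp with bedtools 2.31.1 and with Python 3.11.15 code (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Both gave the same answer for each peak, and the code found all planted overlaps when tested on simulated lists (7308 of 7308 for the vehicle and LNCaP-abl lists in the simulation with the most of them). Shares carry exact Clopper-Pearson 95% intervals. Intervals of ratios of shares come from the exact binomial interval of the peaks of both lists. All intervals cover counting error only and treat peaks as independent, which neighbouring peaks are not. For background, each peak was moved 100 times to a random position on its chromosome and 100 times by 100 to 1000 kb from its own position (seed 1). The random positions on the same chromosome gave between 0.224% and 0.847% of peaks found. Regions were formed by joining overlapping peaks of any list. Score deciles were formed within each list. Peaks per Mb use the length up to the last peak of any list on that chromosome. Figures were drawn with matplotlib 3.10.9.

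The peaks named in the text follow a rule fixed before the data were examined. For each pair of lists these were the 8 highest-scoring peaks of each list without an overlapping peak in the other, and the 5 shared peaks with the highest lower score. Megabases and chromosomes singled out in the text were chosen after their values were seen.

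With 1 library per condition no test between conditions was made. The alternatives tried were a reciprocal overlap of at least 50%, peaks set to 400 bp around their midpoint, the better-scoring 50% of each list, lists of equal length, a common score minimum, and lists without mitochondrial, Y and unplaced sequences. The share of peaks at promoters, 19 gene lists and 19 sequence motifs had been planned. They need an annotation or sequence of hg19 and were left out, because the only reference used here was a RefSeq gene table of assembly GRCh38.p14. That table served to count protein-coding gene names per chromosome, and none of its coordinates were used.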

Results

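TRIM24 occupancy was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 related human prostate cancer cell lines. TRIM24 is a chromatin reader with a PHD finger and a bromodomain that acts as a coregulator of nuclear receptors. LNCaP is an androgen-dependent line from a lymph node metastasis, and LNCaP-abl is a castration-resistant derivative of it that is kept in steroid-depleted medium. LNCaP cells were starved of hormone for 72 h and given ethanol vehicle or 10 nM dihydrotestosterone (DHT), a potent androgen, for 4 h. LNCaP-abl cells received vehicle. Each of the 3 conditions had 1 TRIM24 library, so no difference between conditions has a replicate check and none was tested. The design asks where TRIM24 sat in androgen-dependent cells with and without androgen, and in castration-resistant cells without added androgen. The peak lists give no read numbers and the depth is unknown. Positions are in hg19, and peaks are named by position because no annotation of that build was used here.

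The LNCaP-abl list was the longest of the 3, with 20621 TRIM24 peaks. The vehicle list of LNCaP held 9744 peaks and the DHT list 7105. The LNCaP-abl list was therefore 2.12 times as long as the vehicle list and 2.90 times as long as the DHT list. Its peaks were also wider, with a median of 528 bp against 297 bp under vehicle and 296 bp under DHT. They covered 13.4 Mb of the genome, against 3.51 Mb and 2.48 Mb in the LNCaP lists. The authors' peak scores had a median of 26.1 in LNCaP-abl, 6.46 in LNCaP with vehicle and 6.82 in LNCaP with DHT. Peaks at or above the LNCaP-abl median score numbered 10313 in LNCaP-abl, 337 in LNCaP with vehicle and 307 in LNCaP with DHT. Peak numbers and scores both rise with sequencing depth, which is unknown for these libraries.

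Overlapping peaks of the 3 lists were joined into 22226 regions. TRIM24 regions held by LNCaP-abl alone were the most frequent class, with 11919 regions or 53.6% of the total (95% confidence interval 52.97 to 54.28). All 3 lists shared 4357 regions (19.6%, 19.1 to 20.1). A further 3019 regions were common to LNCaP vehicle and LNCaP-abl, and 1262 to LNCaP DHT and LNCaP-abl. Only 238 regions were common to both LNCaP lists and missing from LNCaP-abl. Part of this class lay on the mitochondrial genome and in 5 windows of 1 Mb beside centromeres, picked after the data were seen. Of the 128 vehicle peaks there, 103 overlapped a DHT peak and 31 a LNCaP-abl peak. The vehicle list alone held 881 regions and the DHT list alone 550. With each list shortened to its 7105 highest-scoring peaks, the LNCaP-abl class fell to 1853 regions, below the 3158 regions then shared by all 3 lists, so that the order of these classes turned over.

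**Figure D1:**
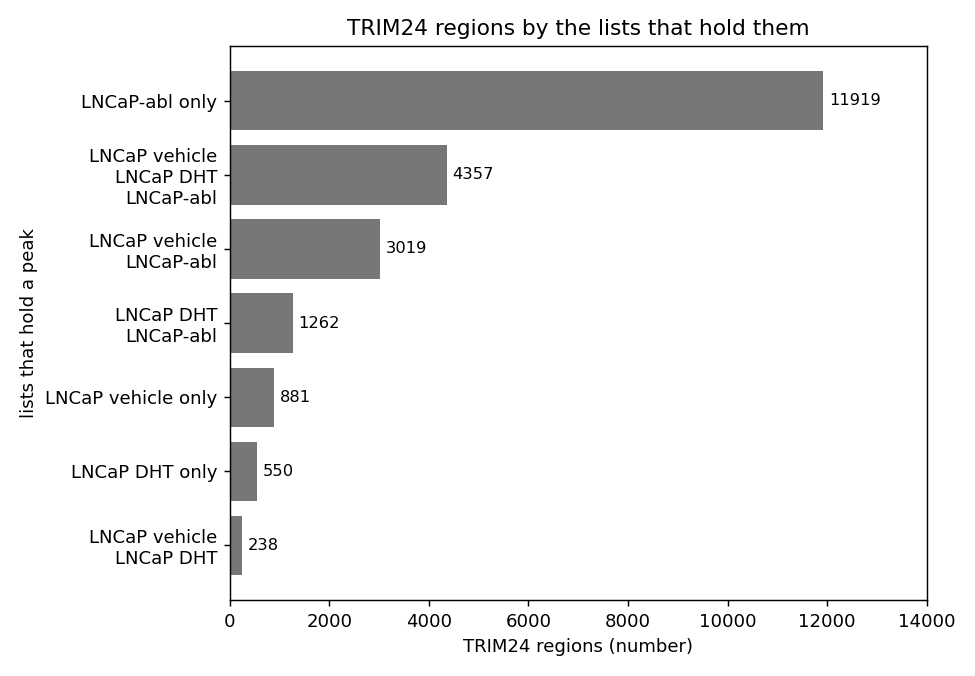
Bars give the number of TRIM24 regions (horizontal axis) in each combination of the 3 peak lists (vertical axis), counted after overlapping peaks were joined. The class held by LNCaP-abl alone has 11919 regions, against 4357 regions shared by all 3 lists and 238 shared by the LNCaP lists alone; in lists of 7105 peaks the first 2 classes hold 1853 and 3158 regions.

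The comparison of DHT with vehicle in LNCaP cells asks which TRIM24 sites go with short androgen exposure. The 2 LNCaP lists shared most of their highest-scoring peaks and fewer of their low-scoring ones. Of the DHT peaks, 4739 (66.7%, 65.6 to 67.8) overlapped a vehicle peak, and 4734 vehicle peaks (48.6%, 47.6 to 49.6) overlapped a DHT peak. Peaks moved at random within 1 Mb of their own position overlapped in 0.491% and 0.373% of cases. The share of vehicle peaks found under DHT was 21.2% (18.7 to 23.9) in the lowest score decile and 95.7% (94.2 to 96.9) in the highest. The share of DHT peaks found under vehicle was 50.5% (46.8 to 54.2) in the lowest decile and 96.3% (94.7 to 97.6) in the highest. Midpoints of vehicle peaks with a DHT partner lay a median of 74.5 bp from it. These shares come from lists of unequal length. With each list at its 7105 highest-scoring peaks, 58.6% (57.5 to 59.8) of DHT peaks overlapped a vehicle peak. Of the vehicle peaks, 57.5% (56.3 to 58.6) then overlapped a DHT peak, so the 2 shares came close together.

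The strongest TRIM24 sites common to vehicle and DHT included chromosome 6 from 170492212 to 170492832, with scores of 245 under vehicle and 195 under DHT. Others lay on chromosome 11 from 66188969 to 66189612, chromosome 1 from 211432190 to 211433341 and chromosome 5 from 177026795 to 177027334. One more, on chromosome 1 from 121483979 to 121485561, borders the centromere of that chromosome. Each of these 5 sites also had a peak in LNCaP-abl. Among 2366 DHT peaks without a vehicle peak, the highest score was 34.3, on chromosome 19 from 7627680 to 7628181. The next lay on chromosome 10 from 124671384 to 124671821, with a score of 26.3, and on chromosome 2 from 220196274 to 220196839, with a score of 24.95. The 8 highest-scoring peaks of this class included 5 with a LNCaP-abl peak. The other 3 lay on chromosome 1 from 26734990 to 26735422, chromosome 16 from 11744117 to 11744411 and chromosome 8 from 10847729 to 10848142. Among 5010 vehicle peaks without a DHT peak, the highest scores were 24.3, on chromosome 11 from 73053673 to 73054465, and 22.9, on chromosome 1 from 16970901 to 16971342. All 8 highest-scoring peaks of this class had a LNCaP-abl peak. The median score was 5.65 in the DHT class and 5.46 in the vehicle class, against 7.73 and 8.52 for the shared peaks of the same lists.

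With all peaks of each list, most of the LNCaP peaks present under a single treatment were present in LNCaP-abl. Of the vehicle peaks without a DHT peak, 4129 (82.4%, 81.3 to 83.5) overlapped a LNCaP-abl peak. Of the DHT peaks without a vehicle peak, 1816 (76.8%, 74.998 to 78.44) did. For peaks shared by both LNCaP lists the share was 94.7% in either list, and for peaks moved within 1 Mb it was between 1.40% and 1.65%. With a reciprocal overlap of at least 50% required in every comparison, the single-treatment classes grew to 6581 vehicle and 3942 DHT peaks. Of these, 19.8% and 15.7% were found in LNCaP-abl. In lists of 7105 peaks the classes held 3021 and 2940 peaks, and the shares were 57.3% (55.5 to 59.1) for vehicle and 48.9% (47.1 to 50.7) for DHT.

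The comparison of LNCaP-abl with LNCaP under vehicle sets castration-resistant against androgen-dependent cells without added androgen. LNCaP-abl held most of the LNCaP set and many TRIM24 sites besides. Of the LNCaP vehicle peaks, 8613 (88.4%, 87.7 to 89.0) overlapped a LNCaP-abl peak. Of the LNCaP-abl peaks, 7421 (36.0%, 35.3 to 36.6) overlapped a vehicle peak. Moving peaks within 1 Mb gave 1.63% and 0.726%. LNCaP-abl peaks with a vehicle peak had a median score of 75.8 and a median width of 898 bp, and those without had 13.6 and 371 bp. The share of LNCaP-abl peaks found under vehicle was 5.33% (4.402 to 6.391) in the lowest score decile and 91.7% (90.4 to 92.9) in the highest.

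**Figure D2:**
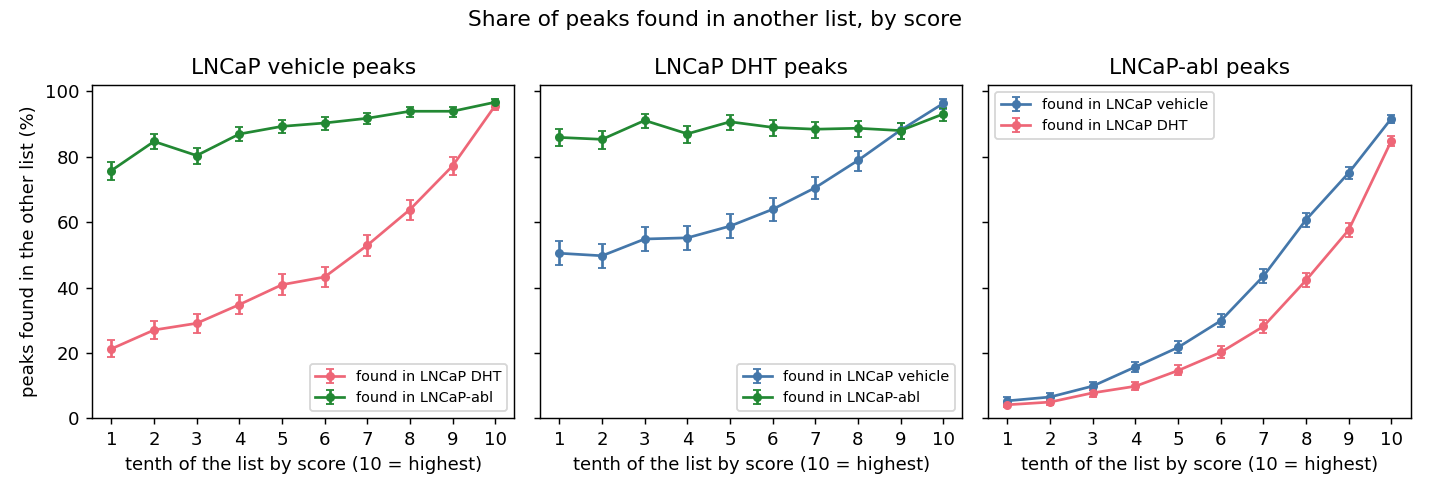
Each panel takes the peaks of 1 list, sorted into 10 groups by the authors' score (horizontal axis), and plots the percentage that overlaps a peak of another list (vertical axis), with exact 95% confidence intervals as bars. LNCaP-abl peaks found in the vehicle list go from 5.33% in the lowest group to 91.7% in the highest, while vehicle peaks found in LNCaP-abl stay between 75.8% and 96.7%.

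The highest-scoring LNCaP-abl site without a vehicle peak lay on chromosome 7 from 27169494 to 27170888, with a score of 266, and had no DHT peak either. Sites on chromosome 8 from 33579604 to 33580313, with a score of 254, and on chromosome 7 from 77045157 to 77046183, with a score of 230.2, were also absent from both LNCaP lists. The site on chromosome 15 from 83735283 to 83736337, with a score of 245, and that on chromosome 17 from 3748955 to 3749849, with a score of 235, had a DHT peak. In all, 5 of the 8 highest-scoring peaks of this class had a DHT peak. In the opposite class, LNCaP vehicle peaks without a LNCaP-abl peak, the highest score was 76.1, on the mitochondrial genome from 15187 to 16571. The next were on chromosome 19 from 56181502 to 56182058, with a score of 55.5, and on chromosome 18 from 18516401 to 18516785, with a score of 35.5, the latter beside the centromere. A further mitochondrial peak, from 1 to 664, had a score of 32.5. The remaining 4 of the 8 highest-scoring peaks lay in crowded groups of LNCaP peaks beside a centromere. They were led by chromosome 10 from 42399275 to 42399650, with a score of 24.2, and the last was chromosome 2 from 92290781 to 92291181, with a score of 22.4. All 8 highest-scoring peaks of this class had a DHT peak. Of those named here, chromosome 18 from 18516401 to 18516785 had a LNCaP-abl peak less than 1 kb away. So did chromosome 10 from 42399275 to 42399650 and chromosome 2 from 92290781 to 92291181. By the lower of their 2 scores, the leading shared sites were chromosome 5 from 177026795 to 177027334, with scores of 272 under vehicle and 776 in LNCaP-abl, and chromosome 6 from 170492212 to 170492832, with scores of 245 and 698. Chromosome 1 from 211432190 to 211433341 came next, with scores of 241 and 734. Chromosome 17 from 80023452 to 80024137 followed, with 177.2 and 793. The last of the 5, chromosome 11 from 66188969 to 66189612, scored lower in LNCaP-abl, with 177.2 under vehicle and 168.9 in LNCaP-abl.

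A pair of settings changed these shares by more than 1.5 times. With a reciprocal overlap of at least 50%, the share of vehicle peaks found in LNCaP-abl fell to 26.3%, below the 32.5% found under DHT, so that the order of the 2 shares was the opposite of the one above. Overlapping peaks of the 2 cell lines differed in width, with medians of 898 bp in LNCaP-abl and 313 bp under vehicle. A peak nested in one more than 2 times as wide cannot meet this rule. With each list at its 7105 highest-scoring peaks, the share of LNCaP-abl peaks found under vehicle rose to 61.0%.

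LNCaP-abl was related to LNCaP under DHT much as it was to LNCaP under vehicle. Of the DHT peaks, 6306 (88.8%, 88.0 to 89.5) overlapped a LNCaP-abl peak, and 5654 LNCaP-abl peaks (27.4%, 26.8 to 28.0) overlapped a DHT peak. Moving peaks within 1 Mb gave 1.47% and 0.507%. The highest-scoring LNCaP-abl site without a DHT peak was again chromosome 7 from 27169494 to 27170888. The next, on chromosome 6 from 76311179 to 76312494 with a score of 254, had a vehicle peak, as did those on chromosome 10 from 70166184 to 70167295 and chromosome 11 from 68518526 to 68519198. DHT peaks without a LNCaP-abl peak were led by the mitochondrial genome from 16041 to 16571, with a score of 48.5, and chromosome 19 from 56181418 to 56182070, with a score of 33.6. Those on chromosome 1 from 11610748 to 11610997 and chromosome 7 from 61970924 to 61971462 followed, with scores of 32.0 and 31.4, the latter in a crowded group of LNCaP peaks beside the centromere. All 8 highest-scoring peaks of this class had a vehicle peak. The share of DHT peaks in LNCaP-abl fell to 24.5% with a reciprocal overlap of at least 50%, and the share of LNCaP-abl peaks under DHT rose to 57.4% in lists of 7105 peaks.

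LNCaP-abl peaks present in both LNCaP lists were the highest-scoring class of that list. These 4373 peaks had a median score of 96.8 and a median width of 1000 bp. The 3048 LNCaP-abl peaks shared with vehicle alone had a median score of 52.6, and the 1281 shared with DHT alone 43.1. The 11919 LNCaP-abl peaks in neither LNCaP list made up 57.8% of the list (57.1 to 58.5), with a median score of 12.3 and a median width of 354 bp.

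TRIM24 peaks were densest on chromosome 19 in each of the 3 lists among the nuclear chromosomes, with 27.8 peaks per Mb in LNCaP-abl, 10.3 under vehicle and 6.79 under DHT. Chromosome 17 followed with 16.5, 7.10 and 5.18 peaks per Mb. Chromosome 19 held 7.96% of the LNCaP-abl peaks and 6.23% of the vehicle peaks, a ratio of 1.28 (1.16 to 1.40). The ratio was 1.504 (1.25 to 1.81) on chromosome X, with 490 and 154 peaks. It was 1.17 (1.04 to 1.32) on chromosome 6, 0.878 (0.784 to 0.985) on chromosome 9, 0.756 (0.632 to 0.905) on chromosome 13 and 0.732 (0.606 to 0.885) on chromosome 18. In lists of 7105 peaks, chromosome 19 went to 0.953 (0.829 to 1.09), on the other side of 1, and chromosome X to 1.05 (0.784 to 1.42). Chromosome 6 was at 1.22 (1.04 to 1.42) in these lists and chromosome 9 at 0.841 (0.715 to 0.989). Chromosomes 13 and 18 were at 0.773 (0.603 to 0.988) and 0.727 (0.559 to 0.943). Chromosome 1 was at 0.918 (0.851 to 0.990) with all peaks and at 0.936 (0.846 to 1.04) in the shorter lists. Chromosome 3 was at 1.01 (0.906 to 1.13) and 1.16 (1.003 to 1.34). The intervals were not adjusted for the number of chromosomes compared.

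**Figure D3:**
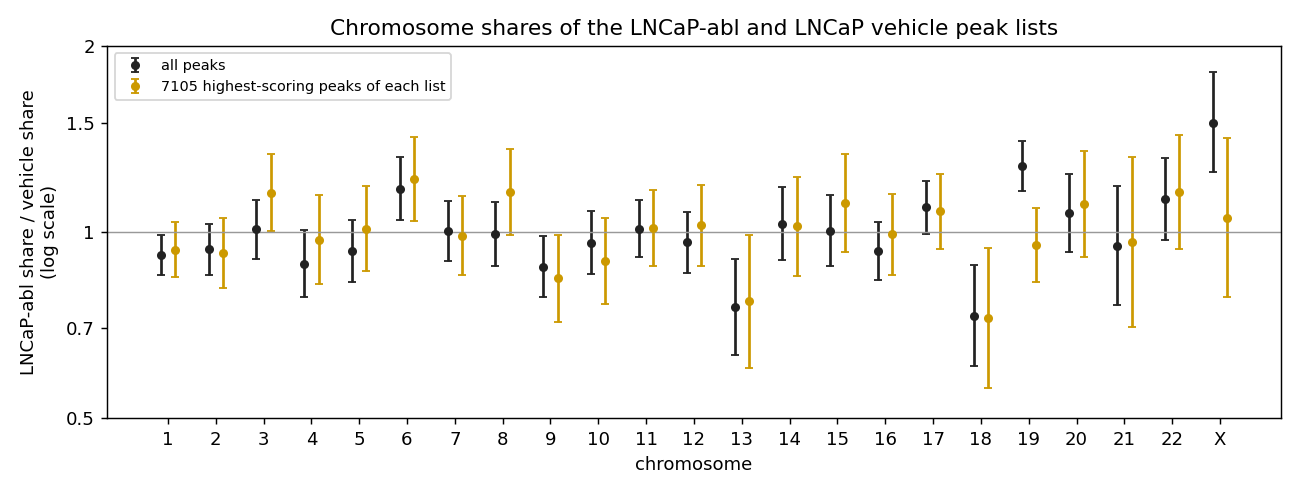
Points give the share of LNCaP-abl peaks on each chromosome (horizontal axis) divided by the share of LNCaP vehicle peaks (vertical axis, log scale), for all peaks and for the 7105 highest-scoring peaks of each list, with 95% confidence intervals as bars. Chromosomes 19 and X stand at 1.28 and 1.504 with all peaks and at 0.953 and 1.05 in lists of equal length, while chromosome 6 stands at 1.17 and 1.22 and chromosome 18 at 0.732 and 0.727.

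The megabase with the most LNCaP-abl peaks was chromosome 19 from 1 to 2 Mb, with 129 peaks, against 44 under vehicle and 25 under DHT. Chromosome 16 from 0 to 1 Mb had the most vehicle peaks, with 50, against 29 under DHT and 72 in LNCaP-abl. Chromosome 10 from 42 to 43 Mb had the most DHT peaks, with 44, and held 43 vehicle peaks and 18 LNCaP-abl peaks. Chromosome 2 from 92 to 93 Mb held 30 vehicle, 29 DHT and 9 LNCaP-abl peaks. The mitochondrial genome held 9 vehicle peaks, 7 DHT peaks and 0 LNCaP-abl peaks.

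**Figure D4:**
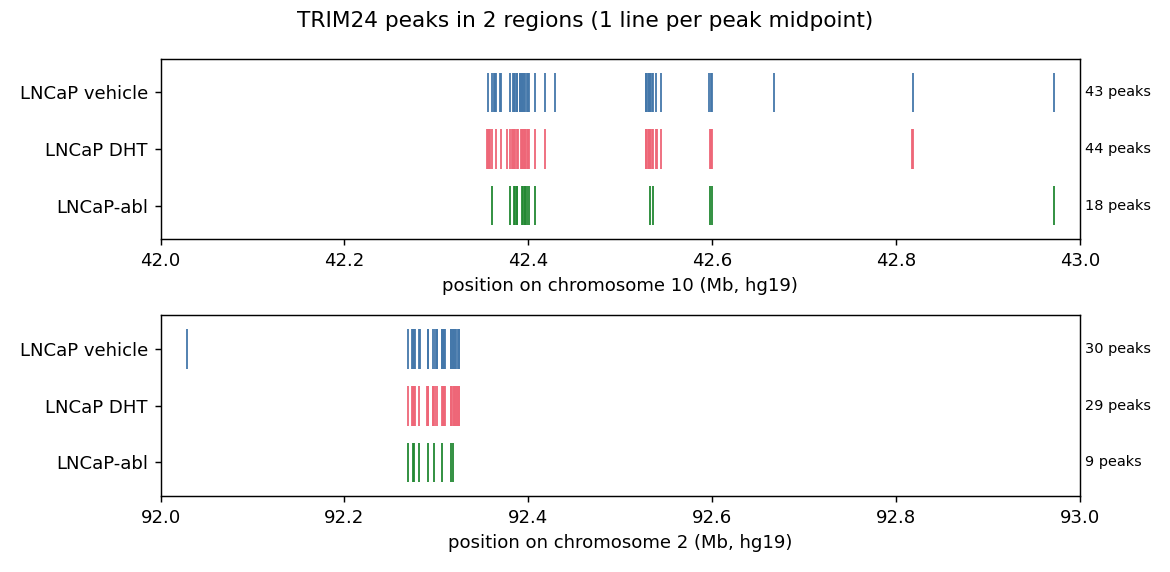
Vertical lines mark the midpoint of each TRIM24 peak between 42 and 43 Mb on chromosome 10 and between 92 and 93 Mb on chromosome 2 (horizontal axes, Mb in hg19), 1 row per peak list. On chromosome 10 there are 43 vehicle, 44 DHT and 18 LNCaP-abl peaks, and on chromosome 2 there are 30, 29 and 9.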

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

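Shares below are given in the order vehicle in DHT, vehicle in LNCaP-abl, DHT in vehicle, DHT in LNCaP-abl, LNCaP-abl in vehicle and LNCaP-abl in DHT. The vehicle-only and DHT-only classes of LNCaP peaks were formed anew in each setting, so their members differ between settings. The joining or matching of peaks less than 1 kb apart and the removal of chrM and 5 windows of 1 Mb with LNCaP clusters were chosen after seeing the data. No paired analysis was possible because each condition had 1 library, and no library could be left out for the same reason. With a reciprocal overlap of at least 50% the shares were 32.5%, 26.3%, 44.5%, 24.5%, 12.4% and 8.44%, and the shares of vehicle-only and DHT-only LNCaP peaks found in LNCaP-abl were 19.8% and 15.7%. LNCaP-abl peaks that overlapped a vehicle peak had a median width of 898 bp, and vehicle peaks that overlapped a LNCaP-abl peak 313 bp. Between LNCaP-abl and DHT these medians were 920 bp and 304 bp. A peak nested in one more than 2 times as wide cannot meet this rule. With peaks of 400 bp the shares were 50.4%, 78.5%, 68.5%, 78.8%, 34.8% and 25.9%, then 71.4% and 66.2%. In the better-scoring 50% of each list they were 46.5%, 83.7%, 63.6%, 78.2%, 36.8% and 25.8%, and 66.1% of DHT-only LNCaP peaks were found in LNCaP-abl. The regions in all 3 lists then numbered 1926 and those in LNCaP-abl alone 5781, as follows from using fewer peaks. In lists of 7105 peaks the shares were 57.5%, 69.4%, 58.6%, 66.3%, 61.0% and 57.4%, then 57.3% and 48.9%, and 1853 regions were in LNCaP-abl alone. The ratio of LNCaP-abl to vehicle shares became 0.953 on chromosome 19, reversing its direction, and 1.05 on chromosome X. Counting peaks less than 1 kb apart as shared gave 59.0%, 90.9%, 75.6%, 90.7%, 41.3% and 31.4%, and 74.8% for DHT-only peaks in LNCaP-abl. Without chrM and the 5 windows, 89.2% of vehicle and 89.9% of DHT peaks were found in LNCaP-abl, and the other 17 results stayed within their intervals or within 1.5 times their counts. At or above a score of 26.1 the lists held 337 vehicle, 307 DHT and 10313 LNCaP-abl peaks. Where no reason is given, the cause was not tested.

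Of the 48 named peaks without a peak in the other list of the pair, 0 gained one with peaks of 400 bp, and 7 had one less than 1 kb away. Some LNCaP-abl sites count under both pairs. Most of the 48 were wider than 400 bp, so that setting shortened them and says little about their absence from the other list. Vehicle peaks were found more often in LNCaP-abl than under DHT in each setting except the reciprocal overlap. The alternatives set for promoter shares, gene lists and motifs were not run, because those results need hg19 annotation or sequence. The unknown depth limits any reading of peak numbers and of absent peaks.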

Other observations

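Several megabases held LNCaP-abl peaks and no LNCaP vehicle peak. Chromosome 19 from 44 to 45 Mb had 14 LNCaP-abl peaks, 0 vehicle peaks and 1 DHT peak (two-sided exact binomial test of the 2 lists, p = 0.00738, Benjamini-Hochberg adjusted p = 1 over 2471 windows). Chromosome X from 54 to 55 Mb had 10 LNCaP-abl, 0 vehicle and 3 DHT peaks (exact p = 0.0366, adjusted p = 1). The same test found 6 windows past an adjusted threshold of 0.05, and in all 6 the vehicle list held the higher share. The 2 directions had unequal power, because the LNCaP-abl list was 2.12 times as long as the vehicle list. On the mitochondrial genome, 9 vehicle and 0 LNCaP-abl peaks gave an exact binomial p of 3.61e-05, lower than the 14 LNCaP-abl and 0 vehicle peaks above. At an unadjusted p under 0.05 there were 48 of 2471 windows, 22 higher in LNCaP-abl and 26 higher in vehicle. That is a smaller share than the cutoff of 0.05 itself, so these counts do not by themselves show regional differences. The test compares 2 peak lists, not conditions, and neighbouring peaks are not independent.

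Of the tests that follow, most were chosen only after the results were seen. These were the tests on the crowded LNCaP windows, on the 700 highest-scoring peaks and the highest score decile, on peak width and on gene density. The repeat of the last in lists of equal length was also chosen after. The test on joined peaks and that on the length of the DHT list were set before. A first form of the tests on crowded windows, built on the longest stretch without peaks of each chromosome, was dropped because it missed the gaps at the centromeres of chromosomes 2, 4, 10 and 11.

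The greater number of TRIM24 peaks in LNCaP-abl could come from a lower detection limit there or from more bound sites. Peaks called in pieces are argued against, because joining peaks less than 1 kb apart left the LNCaP-abl list 2.20 times as long as the vehicle list. Of the 700 highest-scoring LNCaP-abl peaks, 97.4% (96.0 to 98.5) were found under vehicle, against 96.3% (94.6 to 97.6) of the 700 highest-scoring DHT peaks, but in the highest score decile of each list the order was the opposite, with 91.7% (90.4 to 92.9) and 96.3% (94.7 to 97.6). Since the lists differ in length and the shares are near their ceiling, neither comparison decides on a detection limit in the LNCaP libraries, which stays open together with a difference between the cell lines. The exceptions are few, since 9 of the 700 LNCaP-abl peaks, among them chromosome 7 from 27169494 to 27170888, were in neither LNCaP list.

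The 6 windows with a higher vehicle share were chromosome 10 from 42 to 43 Mb, chromosome 2 from 92 to 93 Mb, chromosome 4 from 49 to 50 Mb, chromosome 11 from 51 to 52 Mb, chromosome 7 from 61 to 62 Mb and the mitochondrial genome, and the 5 nuclear ones lie beside centromeres. They held 128 vehicle, 124 DHT and 35 LNCaP-abl peaks, and nuclear vehicle peaks there were a median of 1000 bp apart, against 81037 bp elsewhere. Random calls spread evenly within groups of LNCaP peaks less than 10 kb apart are argued against. Of these vehicle peaks, 80.5% (72.5 to 86.9) recurred under DHT, and at most 47.7% (mean 37.1%) did in 100 random placements within their own groups. The placements were even along each group, so background that recurs at the same spots in both LNCaP libraries was not excluded. A copy number change that lowers the LNCaP-abl share of peaks across the neighbouring 10 Mb is argued against. The LNCaP-abl to vehicle ratio of shares there was 1.04 (0.897 to 1.22). In the 5 windows the ratio was 0.139 (0.0925 to 0.204), but they were chosen for their difference between these lists, so that value is no evidence. A copy number change in these windows or beside some of them remains open. So do reads from repeats missing from the assembly and a different control or background in the LNCaP libraries. None of these was tested, as the hg19 sequence and the inputs were not used here, and no biological explanation was tested.

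DHT peaks found in neither other list lay in the upper 50% of their list by score in 34.0% of cases (30.0 to 38.1, 187 of 550), against 18.2% (15.7 to 20.9) for the corresponding vehicle peaks. The 7105 highest-scoring vehicle peaks gave 19.8% (15.9 to 24.3), so this cut did not bring the vehicle share up to the DHT share. DHT peaks were still compared with the full vehicle list of 9744 peaks, which held 50.5% of the lowest DHT score decile. Of the lowest vehicle decile, 21.2% was found under DHT. The test therefore cannot decide whether the unequal list lengths are the reason. Of the 187 DHT peaks, 84.5% (78.5 to 89.4) were narrower than the median of 50 shared peaks of like score, as were 83.8% (77.1 to 89.1) of the corresponding vehicle peaks, so narrowness is not particular to DHT. The unequal list lengths, random calls and stacks of duplicate reads stay open, as does the hypothesis of an effect of DHT. The highest-scoring sites to examine are chromosome 1 from 26734990 to 26735422 and chromosome 16 from 11744117 to 11744411.

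A hypothesis on the chromosome make-up is that LNCaP-abl gained TRIM24 peaks on gene-rich chromosomes. Over 22 autosomes and X, the LNCaP-abl to vehicle ratio of shares rose with protein-coding gene names per Mb (GRCh38.p14 names, Spearman's rho 0.59, two-sided permutation p = 0.00346, adjusted p = 0.00519 over 3 relations). Pearson's r was 0.468 (permutation p = 0.0821, adjusted p = 0.175) and 0.303 without chromosomes 17 and 19, the farthest from the median density. Without chromosome X, r was 0.708 and rho 0.66. For DHT against vehicle, rho was -0.20 (permutation p = 0.355, adjusted p = 0.355), and for LNCaP-abl against DHT it was 0.63 (permutation p = 0.00174, adjusted p = 0.00519). In lists of 7105 peaks, rho for LNCaP-abl against vehicle was 0.34 (permutation p = 0.112) and r was 0.14 (permutation p = 0.538), and without chromosomes 17 and 19 they were 0.41 and 0.42. The test thus missed the threshold at this length, and the relation is not shown apart from the low-scoring peaks that the longer LNCaP-abl list adds. Chromosomes are not independent replicates of the condition.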
